A study of Mus musculus with 16 samples.

How the data were processed

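RNA of 8 sorted mouse cell populations had been measured on Agilent miRNA arrays with the Cy3 dye, 2 biological replicates per population, each a pool of animals, per the labels. Replicate 1 of every population lay on array design 1 and replicate 2 on array design 2, so the replicate number, the design and the slide are the same split of the 16 arrays, 8 on each design. Design 1 holds 650 miRNAs (611 of mouse and 39 viral) and design 2 holds 696. Each miRNA has 20 spots spread over 1 to 4 probes.

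The intensity of each spot had been read from the scan and its background removed by Agilent Feature Extraction 10.7.3.1, per the file headers. The submitters' processing notes name version 9.1. The values used are the processed signals as deposited in these array files, on a linear scale, not logged and not scaled between arrays. The series tables hold the same signals as deposited, rounded to 3 significant digits, and all 13715 spots of each design 1 array and 14635 of each design 2 array were equal at that precision.

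Spots that Feature Extraction had marked as non-uniform or population outliers were left out, the remaining spots of a probe were averaged, and the probes of a miRNA were averaged on the linear scale. A miRNA counted as detected on an array where, for any of its probes, at least a share of 0.5 of the spots was well above background. The 604 miRNAs on both designs had identical probe sequences on both. Left out of the comparisons were 7 mouse miRNAs on design 1 alone, 92 on design 2 alone and the 39 viral ones. Each array was divided by the 75th percentile of the 88 miRNAs detected on all 16 arrays, a factor between 333 and 876. Values below a floor were raised to it. The floor was the median over the arrays of a design of the 5th percentile of detected values, on the log2 scale -5.32 for design 1 and -5.78 for design 2. The 175 miRNAs detected on both arrays of at least 1 population were tested, of which 21 to 56 per array lay at the floor. A population is called not above background for a miRNA that was detected on 0 of its arrays, and a fold against it is given as a lower bound, with the dim side set on each array to its measured value or to the lowest signal of a detected probe, whichever was higher. Probe positions are those of the file headers' build, mm9.

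The log2 values were fitted with limma 3.58.1 in R 4.3.3, with a mean for each population, the array design as a block and moderated variances (8.52 residual degrees of freedom after moderation). The numbers pair the samples because they mark the array design. The deviations of same-numbered arrays from their population means correlated across miRNAs in all 28 pairs of populations, with r from 0.293 to 0.916 and a median of 0.570. The median absolute difference between replicates was 0.35 on the log2 scale and 0.18 after the mean difference between the designs was removed. A moderated F test compared all 8 populations, and 10 contrasts compared MDP with MP, CDP with MDP, Gr1+ monocytes with MDP, PDC with CDP, the mean of the 3 spleen DC with CDP, CD8+ DC with the mean of the other spleen DC, CD4+ with CD4-CD8- DC, PDC and Gr1+ monocytes each with the mean of the spleen DC, and the 5 differentiated with the 3 progenitor populations. The p-values were adjusted by the method of Benjamini and Hochberg within each comparison, and a miRNA is called higher or lower where the adjusted p is under 0.05.

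Before the data were examined, 13 miRNA lists were fixed: stem and early progenitor, myeloid, activation, lymphocyte, erythroid, and stromal, muscle and epithelial miRNAs, the miR-17 clusters, the let-7, miR-15 and miR-16, miR-29 and miR-30 families, both arms of miR-142, and the Dlk1-Dio3 locus. The 9 lists with at least 3 tested members were tested with camera of limma at its preset correlation between miRNAs, again with a correlation estimated from the data, and with fry, each adjusted over the 90 tests. Camera sets a list against the other tested miRNAs and fry sets it against no change, so their directions can differ. The other 4 lists are given per member. The rule for naming miRNAs was also fixed before: the 10 with the largest rise and the 10 with the largest fall among those called with the same sign in both replicates, the 20 with the smallest p in the F test, up to 4 members per list with the smallest p, the 10 with the highest mean value per design, and in every comparison miR-142-3p, miR-142-5p, miR-223, miR-150, miR-155, miR-146a, miR-21, miR-126-3p and miR-181a. Further list members, miR-451 and the neighbours of miR-532-5p on chromosome X were named after their values were seen.

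The statistics were tested on simulated arrays with changes placed in MDP against MP. In 20 runs with 60 of 175 miRNAs changed, 63.8 percent of changes by 0.6 on the log2 scale were called, 85.0 percent of changes by 1 and 97.2 percent of changes by 2. Of the calls, 3.81 percent were false. The simulated errors were independent and normal, with the spread fitted to the real arrays. They had no floor, no scaling step and no error shared within an array. These rates therefore describe the model under its own assumptions and not the real arrays.

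The alternatives tried were scaling over all miRNAs of the array, quantile normalization within each design, normexp background correction with an offset of 50, the brightest probe of each miRNA, Feature Extraction's total signal per miRNA, the series tables, no filter on dim miRNAs, only miRNAs detected on all arrays, no block, an intensity trend with robust moderation, and leaving out each array in turn. Files were read with the R packages data.table, version 1.17.8, and jsonlite 2.0.0, and figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.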

Results

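MicroRNA (miRNA) levels were measured on 1-colour arrays in 8 cell populations, each sorted without culture from female C57Bl/6 mice aged 6 weeks. Each population had 2 biological replicates, which makes 16 arrays, and each replicate was RNA of a pool of animals. The progenitors came from bone marrow in pools of 15 mice. All 3 were negative for lineage markers and positive for CD135. MP cells were CD117+ CD115-, macrophage and dendritic cell progenitors (MDP) CD117+ CD115+, and common dendritic cell progenitors (CDP) CD117 low CD115+. The labels do not spell out MP. Gr1+ monocytes and plasmacytoid dendritic cells (PDC) came from bone marrow in pools of 5 mice, and CD4+, CD8+ and CD4-CD8- dendritic cells (DC) from spleen in pools of 8. The CD8+ DC were also gated on CD86, which the labels list for no other population. Replicate 1 of every population lay on array design 1 and replicate 2 on design 2.

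Between 16.7 and 25.4 percent of the spots were well above background on each array, and 0 spots were saturated. Of the 604 miRNAs on both designs, 116 to 174 were detected per array and 88 on all 16 arrays. The comparisons used the 175 miRNAs detected on both arrays of at least 1 population. Values are log2 signals relative to the 75th percentile of the array. Group means are given ± SD (n = 2), an SD that includes the offset between the array designs, and log2 differences are given ± SE. The number of arrays limits the precision. Values raised to the floor have no spread of their own. For miRNAs at the floor in many populations the SE and adjusted p can therefore be too small. Where the lower side was detected on only some of its arrays, the size of the difference is limited by the floor and no lower bound is given. The 10 miRNAs with the highest mean signal included miR-223, let-7f, let-7a, miR-15b, miR-21, miR-709, miR-16, miR-92a and let-7i on both designs, miR-142-3p on design 1 and let-7d on design 2. They are given by name only, because signals of different probes are not comparable as levels.

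The replicates were set against each other after the mean of each design was removed. For 15 of the 16 arrays, the array of the other design with the highest correlation was that of the same population (Pearson r across 175 miRNAs, which are not independent replicates). The correlation between a population's own arrays ran from 0.807 in CD4-CD8- DC to 0.928 in CDP. The exception was replicate 1 of CD4-CD8- DC, whose correlation with replicate 2 of CD4+ DC and with its own replicate 2 was 0.807 each, the former higher in the later digits. With the 88 miRNAs detected on all arrays, 14 of the 16 arrays matched their own population best.

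**Figure D1:**
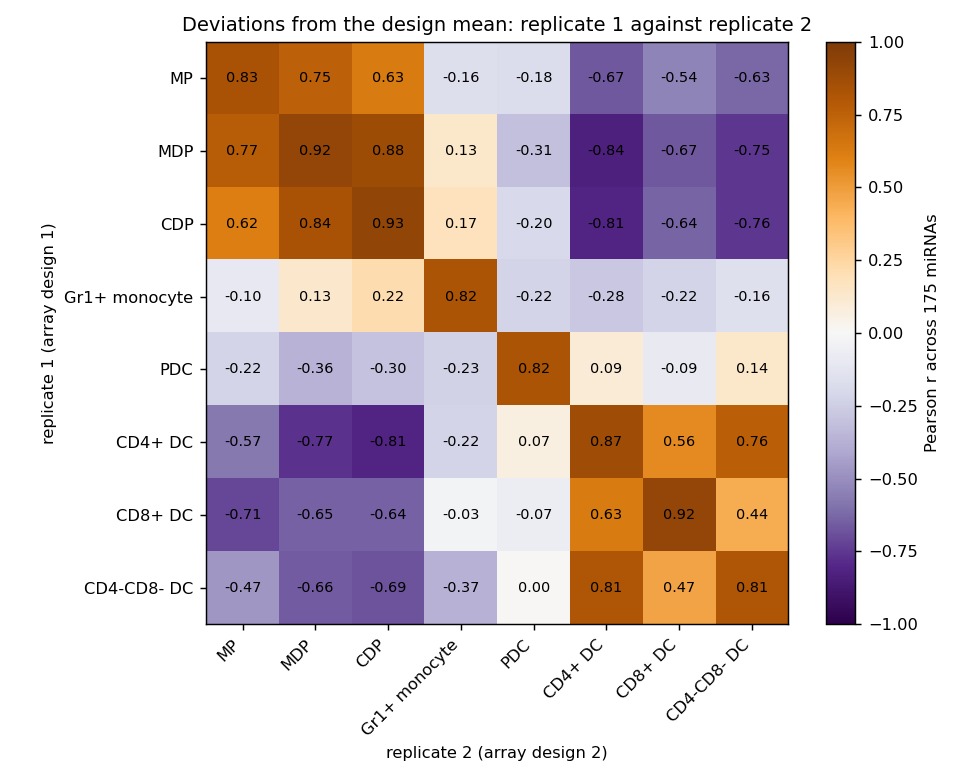
Pearson correlation across 175 miRNAs of each replicate 1 array (vertical axis, array design 1) with each replicate 2 array (horizontal axis, array design 2), after the mean of each design was removed; each cell prints its r. The diagonal runs from 0.807 to 0.928. The highest value off it is 0.879, between MDP and CDP, and among the spleen DC 0.807, between CD4-CD8- DC and CD4+ DC.

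The first question was whether miRNA levels differed among the populations at all. A moderated F test over the 8 group means called 130 of 175 miRNAs. The 20 with the smallest p were miR-22, miR-181b, miR-151-5p, miR-146a, miR-138, miR-350, miR-34a, miR-20a, miR-29a, miR-15a, miR-126-3p, miR-181a, miR-196b, miR-148a, miR-92a, miR-342-3p, miR-20b, miR-221, miR-27b and miR-29c. miR-22 (adjusted p = 5.86e-07) was not above background in MDP. The mean of miR-146a differed by 5.99 on the log2 scale between its highest and lowest population (adjusted p = 1.55e-06) and that of miR-34a by 5.13 (adjusted p = 1.67e-06). The highest mean among the called miRNAs lay in CD8+ DC for 43 and in MP for 24. It lay in CD4+ DC and in PDC for 18 each, in Gr1+ monocytes for 14 and in CDP for 5. MDP and CD4-CD8- DC had 4 each. These counts are those of the main scaling, and the balance of the CD8+ DC calls turned under the other scalings, as given below. Per the file headers, the probes of miR-22 lie on chromosome 11 (75277278 to 75277295), of miR-146a on chromosome 11 (43187908 to 43187925), of miR-34a on chromosome 4 (149442585 to 149442603) and of miR-223 on chromosome X (93438225 to 93438244), in mouse build mm9. With normexp background correction 53 miRNAs were called, and 81 of the 88 detected on all arrays were called when only those were tested.

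Several miRNAs with known places in blood cells separated the populations. miR-223, a myeloid miRNA, had its highest mean in Gr1+ monocytes (4.42 ± 0.17) and its lowest in PDC (0.30 ± 0.30). miR-126-3p, a miRNA of stem and progenitor cells, was -1.62 ± 0.08 in MP, -2.54 ± 0.08 in MDP and -2.90 ± 0.21 in CDP, and was not above background in Gr1+ monocytes or in any spleen DC population. miR-146a was highest in CD4+ DC (1.15 ± 0.00) and was -4.84 ± 0.02 in CDP. miR-181a, known from lymphoid cells, was highest in PDC (0.72 ± 0.16).

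**Figure D2:**
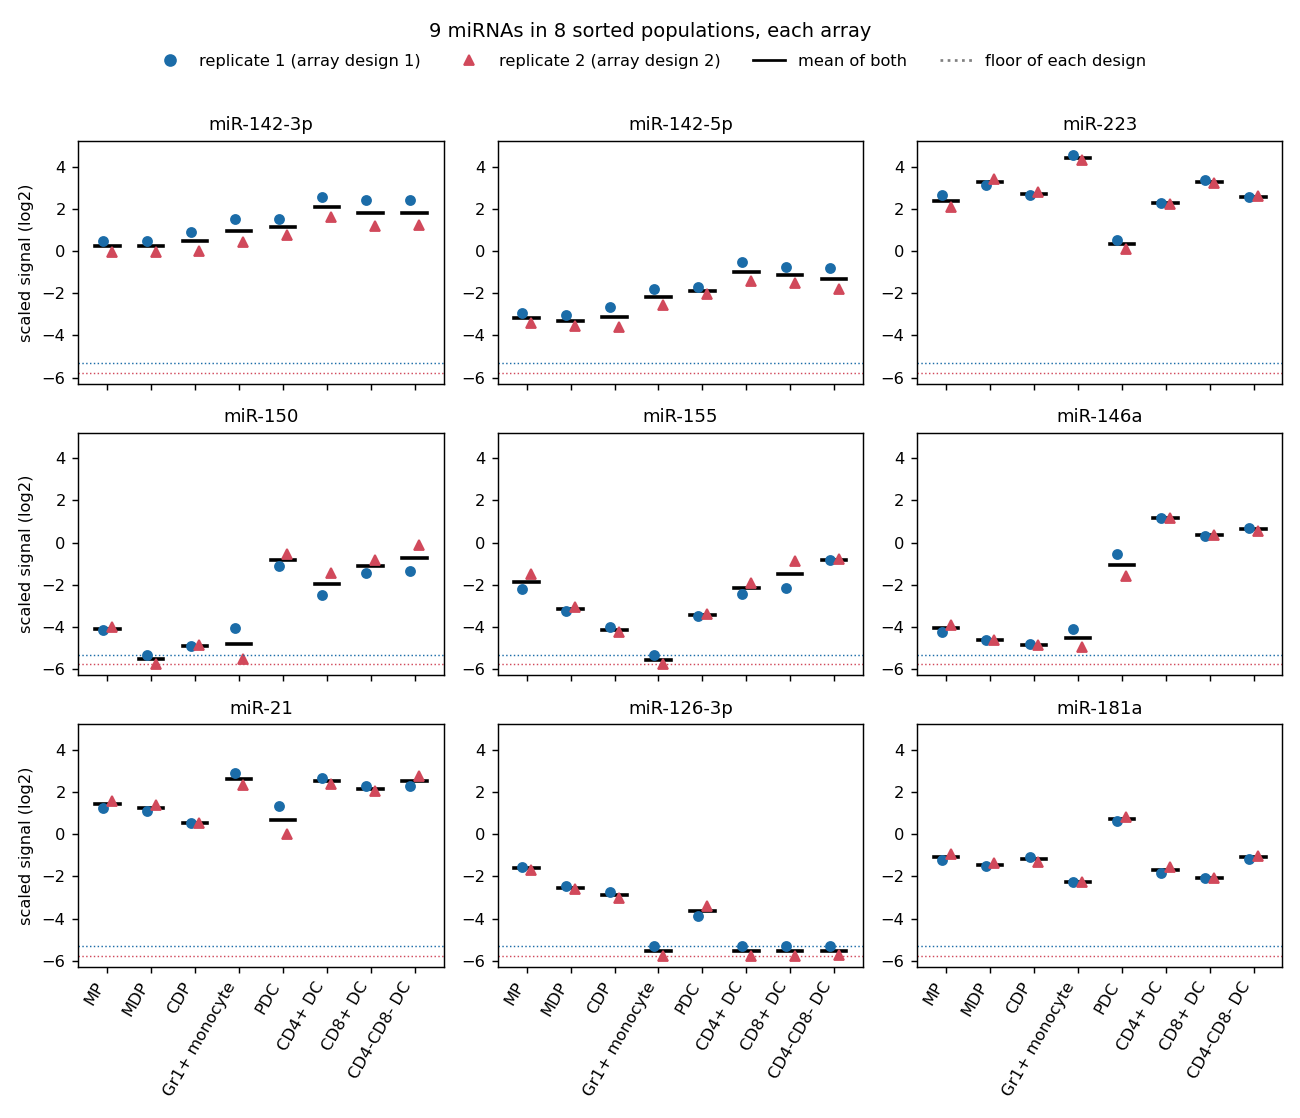
Scaled signal (log2, relative to the 75th percentile of the array) of the 9 miRNAs named in every comparison, per array in the 8 populations. Circles are replicate 1, triangles replicate 2, bars the mean of both (n = 2) and dotted lines the floor of each array design. miR-223 is lowest in PDC, and miR-126-3p is not above background in Gr1+ monocytes or in any spleen DC population.

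MDP were compared with MP to ask what changes between adjacent progenitors that differ in CD115. miR-130a fell (-1.74 ± 0.33, adjusted p = 0.027), as did miR-196b, which lies within a Hox cluster (-1.60 ± 0.21, adjusted p = 0.00777), let-7e (-1.74 ± 0.33, adjusted p = 0.027) and miR-125b-5p (-1.10 ± 0.28, adjusted p = 0.0386). let-7e was not above background in MDP and was at least 1.83-fold lower there. miR-126-3p also fell (-0.92 ± 0.22, adjusted p = 0.0368), and miR-223 was the miRNA that rose (0.91 ± 0.20, adjusted p = 0.027). In all, 18 miRNAs were called, 1 higher and 17 lower, 6 of the latter on the stem and early progenitor list. Further miRNAs called lower were miR-128 (-1.30), miR-322 (-0.96), miR-99a (-0.95), miR-146b (-0.84) and miR-450a-5p (-0.83), the last not above background in MDP and at least 1.12-fold lower. Under normexp background correction miR-450a-5p turned (0.02, not called). Neither miR-155 (-1.31 ± 0.36, adjusted p = 0.0517) nor miR-150 (-1.45 ± 0.56, adjusted p = 0.144) was called, nor were miR-142-3p, miR-142-5p, miR-146a, miR-21 and miR-181a. miR-451, an erythroid miRNA, was not above background in MDP and was not called (-2.16 ± 1.08, adjusted p = 0.286).

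Among the fixed lists, the stem and early progenitor associated miRNAs had 7 tested, 0 higher, 6 lower and 1 not called, with 7 called adjusted over the list alone (median log2 difference -1.13, and -0.999 and -1.32 within array designs 1 and 2; camera adjusted p = 3.21e-05, and adjusted p = 0.534 with an estimated correlation), with a median of -0.75 under quantile normalization. Examples were miR-196b, miR-130a, let-7e and miR-99a. The let-7 family had 9 tested, 0 higher, 3 lower and 6 not called, with 6 called adjusted over the list alone, with camera adjusted p = 0.00654, and adjusted p = 0.534 with an estimated correlation, examples let-7e, let-7c and let-7b, and a median of -0.27 that turned to 0.00 when arrays were scaled over all miRNAs. The miR-29 family had 3 tested, 0 higher, 2 lower and 1 not called, with 3 called adjusted over the list alone, with median -0.59, camera adjusted p = 0.0378, and adjusted p = 0.534 with an estimated correlation, a median of -0.31 when scaled over all miRNAs, and examples miR-29c and miR-29a. The miR-30 family had 5 tested, 0 higher, 1 lower and 4 not called, with 4 called adjusted over the list alone, with camera adjusted p = 0.0308, and adjusted p = 0.534 with an estimated correlation, examples miR-30e and miR-30b, and a median of -0.40 that turned to 0.04 under quantile normalization. Of the 18 calls, 0 were also made under both other scalings: 0 miRNAs were called when arrays were scaled over all their miRNAs, and 9 under quantile normalization (2 higher and 7 lower). Scaled over all miRNAs, the difference was -1.47 for miR-130a, -1.32 for miR-196b, -1.52 for let-7e and 1.19 for miR-223, so that these directions were kept without a call. Under quantile normalization the difference of miR-223 was 0.47 (adjusted p = 0.404). Leaving out MDP replicate 1 left 0 calls, MDP replicate 2 left 2 and MP replicate 2 left 2, while 9 were called without the block on the array design, 9 from the brightest probe of each miRNA and 0 with normexp.

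CDP, which carry less CD117, were compared with MDP. limma called 0 of 175 miRNAs, and 26 had an unadjusted p under 0.05. The smallest adjusted p belonged to miR-196b (-1.03 ± 0.21, adjusted p = 0.182), and miR-130a (-0.98 ± 0.33, adjusted p = 0.24), miR-223 (-0.56 ± 0.20, adjusted p = 0.24) and miR-155 (-0.97 ± 0.36, adjusted p = 0.24) were not called either, nor were the other miRNAs named in every comparison. The stem and early progenitor list had 7 tested, 0 higher, 0 lower and 7 not called, with 3 called adjusted over the list alone (median log2 difference -0.77, and -0.64 and -0.82 within array designs 1 and 2; camera adjusted p = 0.00392, and adjusted p = 0.534 with an estimated correlation), with the smallest p in miR-196b, miR-99a, miR-130a and miR-125b-5p. Its median was -0.30 when scaled over all miRNAs. The lymphocyte list had 7 tested, 0 higher, 0 lower and 7 not called, with 0 called adjusted over the list alone (median log2 difference 0.25, and 0.42 and 0.05 within array designs 1 and 2; camera adjusted p = 0.015, and adjusted p = 0.534 with an estimated correlation), led by miR-342-3p and miR-181b, with medians of 0.72 when scaled over all miRNAs and 0.42 under quantile normalization. Scaling over all miRNAs gave 1 call, miR-181b (0.85, adjusted p = 0.0389, against 0.38 in the main scaling). Quantile normalization gave 3, all higher in CDP. Among them were miR-181b (0.51, adjusted p = 0.0321) and miR-342-3p (0.82 in the main scaling, 1.39 under quantile normalization).

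Gr1+ monocytes were compared with MDP to see what accompanies monocyte formation within marrow. miR-22 rose most (4.36 ± 0.21, adjusted p = 2.58e-06) and, as it was not above background in MDP, was at least 11.3-fold higher in monocytes. miR-15a (1.64 ± 0.11, adjusted p = 8.72e-06), miR-16 (1.64 ± 0.11, adjusted p = 8.72e-06) and miR-342-3p (1.99 ± 0.29, adjusted p = 0.000674) rose as well. Several miRNAs of early progenitors fell. miR-126-3p (-3.01 ± 0.22, adjusted p = 1.49e-05), miR-130a (-2.77 ± 0.33, adjusted p = 0.000241) and miR-196b (-2.53 ± 0.21, adjusted p = 2.89e-05) were not above background in monocytes and were at least 5.84-fold, 4.93-fold and 4.18-fold lower there. miR-155 was likewise not above background in monocytes and at least 3.79-fold lower (-2.39 ± 0.36, adjusted p = 0.00079). With normexp the differences of miR-196b (0.08) and miR-155 (0.19) turned and were not called. miR-223 rose by 1.15 ± 0.20 (adjusted p = 0.00142), a call that ended under quantile normalization (0.00), which sets the highest values of all arrays of a design to the same level.

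Of 175 miRNAs, 66 were called, 35 higher and 31 lower. Others higher in monocytes were miR-532-5p (1.62), miR-185 (1.51), miR-21 (1.37), miR-139-5p (1.36), miR-350 (1.27), miR-142-5p (1.12) and miR-142-3p (0.74). Of these, miR-532-5p, miR-185 and miR-139-5p were not above background in MDP and at least 1.69-fold, 1.69-fold and 1.46-fold higher in monocytes. The calls of miR-21 and miR-142-3p ended without MDP replicate 1 (1.13 and 0.52) and without monocyte replicate 1 (1.15 and 0.63), that of miR-21 under quantile normalization (0.86) and that of miR-142-3p when scaled over all miRNAs (0.71). The call of miR-139-5p ended when any of the 4 arrays was left out, at 1.18 to 1.54. Others lower were miR-92a (-1.42), miR-125b-5p (-1.53), miR-99a (-1.60), miR-181a (-0.82), miR-181b (-1.56), miR-181c (-1.63) and miR-181d (-1.96), while miR-146a and miR-150 were not called. Turned and not called with normexp were miR-125b-5p (0.05), miR-99a (0.33), miR-181c (0.28) and miR-181d (0.01). The miR-17 family clusters had 10 tested, 0 higher, 7 lower and 3 not called, with 8 called adjusted over the list alone (median log2 difference -1.18, and -0.82 and -1.46 within array designs 1 and 2; camera adjusted p = 0.000331, and adjusted p = 0.534 with an estimated correlation), with miR-92a, miR-20a and miR-20b as examples. The stem and early progenitor list had 7 tested, 0 higher, 5 lower and 2 not called, with 5 called adjusted over the list alone (median log2 difference -1.60, and -1.61 and -1.78 within array designs 1 and 2; camera adjusted p = 0.00392, and adjusted p = 0.534 with an estimated correlation), with miR-126-3p and miR-196b as examples. The miR-15 and miR-16 family had 5 tested, 4 higher, 0 lower and 1 not called, with 4 called adjusted over the list alone (median log2 difference 0.93, and 1.12 and 0.90 within array designs 1 and 2; camera adjusted p = 0.00446, and adjusted p = 0.534 with an estimated correlation), with miR-15b and miR-195 beside miR-15a and miR-16. With normexp 11 miRNAs were called.

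PDC were compared with CDP, both from marrow, to see what accompanies formation of plasmacytoid cells. miR-150, known from mature lymphocytes, rose (4.05 ± 0.56, adjusted p = 0.000308), as did miR-146a (3.77 ± 0.31, adjusted p = 1.37e-05), miR-128 (3.81 ± 0.27, adjusted p = 5.5e-06) and miR-181a (1.91 ± 0.13, adjusted p = 5.5e-06). miR-362-3p (4.14 ± 0.28, adjusted p = 5.5e-06) and miR-532-5p (4.12 ± 0.24, adjusted p = 5.5e-06), which are neighbours on chromosome X, rose as well. miR-362-3p, not above background in CDP, was at least 13.7-fold higher in PDC, and miR-532-5p was detected on 1 of the 2 CDP arrays. miR-223 fell (-2.40 ± 0.20, adjusted p = 1.37e-05), and so did the miR-17 family members miR-18a (-2.61 ± 0.19, adjusted p = 5.5e-06) and miR-17 (-1.91 ± 0.17, adjusted p = 2.28e-05).

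Of 175 miRNAs, 66 were called, 45 higher and 21 lower. Scaled over all miRNAs of the array the split was 26 higher and 39 lower, and under quantile normalization 36 and 32. Under both, 47 of the calls kept their direction and threshold (26 higher and 21 lower), and 6 turned under one or the other. Others higher were miR-22 (3.27), miR-500 (3.18), miR-592 (2.61) and miR-151-5p (2.45), of which miR-592 and miR-151-5p were not above background in CDP and at least 4.74-fold and 4.24-fold higher in PDC, while miR-22 was detected on 1 of the 2 CDP arrays. miR-142-5p (1.26) and miR-142-3p (0.68) were called higher, calls that ended when arrays were scaled over all miRNAs (0.73 and 0.15). The call of miR-142-3p also ended without either CDP array (0.68 and 0.67) or PDC replicate 2 (0.60). Others lower were miR-19a (-1.80), miR-19b (-1.28), miR-20a (-1.72), miR-20b (-1.51), miR-27b (-1.53), miR-221 (-1.33) and miR-99a (-1.21). miR-126-3p was called lower (-0.74 ± 0.22, adjusted p = 0.0243), a call that ended without PDC replicate 1 (-0.33) or either CDP array (-0.70 and -0.79). miR-155 and miR-21 were not called. The erythroid miR-451 was not called (2.70 ± 1.08, adjusted p = 0.0907) but was called higher without PDC replicate 1 (3.92). Members of the miR-17 family clusters had 10 tested, 0 higher, 8 lower and 2 not called, with 8 called adjusted over the list alone (median log2 difference -1.39, and -1.51 and -1.27 within array designs 1 and 2; camera adjusted p = 1.07e-05, and adjusted p = 0.534 with an estimated correlation). The miR-29 family had 3 tested, 3 higher, 0 lower and 0 not called, with 3 called adjusted over the list alone (median log2 difference 2.20, and 1.91 and 2.50 within array designs 1 and 2; camera adjusted p = 0.015, and adjusted p = 0.534 with an estimated correlation), made up of miR-29a (2.02), miR-29b (2.20) and miR-29c (2.48). The lymphocyte list had 7 tested, 4 higher, 0 lower and 3 not called, with 4 called adjusted over the list alone (median log2 difference 1.43, and 1.17 and 1.49 within array designs 1 and 2; camera adjusted p = 0.189, and adjusted p = 0.719 with an estimated correlation), the higher members being miR-150, miR-181a, miR-181c (1.43) and miR-342-3p (1.61). With normexp 31 miRNAs were called.

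The mean of the 3 spleen DC populations was compared with CDP. Tissue and cell type change together here, since CDP came from marrow. miR-146a, a brake on inflammatory signalling, rose (5.55 ± 0.25, adjusted p = 4.49e-07), as did miR-34a (4.48 ± 0.23, adjusted p = 5.86e-07) and miR-22 (4.90 ± 0.17, adjusted p = 1.77e-07), which was detected on 1 of the 2 CDP arrays. miR-151-5p (3.83 ± 0.18, adjusted p = 4.49e-07) was not above background in CDP and at least 11.1-fold higher in spleen DC. miR-155, known from activated immune cells, rose (2.63 ± 0.29, adjusted p = 5.62e-05), and so did both arms of miR-142, a miRNA of blood cells in general (miR-142-5p 1.98 ± 0.14, adjusted p = 4.19e-06; miR-142-3p 1.44 ± 0.15, adjusted p = 3.84e-05). miR-126-3p (-2.64 ± 0.18, adjusted p = 3.23e-06) was not above background in spleen DC and was at least 4.84-fold lower there, and miR-181b fell (-2.83 ± 0.12, adjusted p = 4.22e-07).

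Of 175 miRNAs, 99 were called, 65 higher and 34 lower, and the median log2 difference over all of them was 0.26. The split was 30 higher and 52 lower when arrays were scaled over all miRNAs, and 43 and 41 under quantile normalization. Under both, 64 calls kept their direction and threshold (30 higher and 34 lower), and 14 turned under one or the other. Others higher were miR-342-3p (3.31), miR-150 (3.61), miR-29a (2.14), miR-29c (2.65), miR-21 (1.88) and the erythroid miR-451 (3.67 ± 0.88, adjusted p = 0.00598), whose call ended without CDP replicate 1 (3.61). Others lower were miR-17 (-1.81), miR-18a (-1.98), miR-20a (-1.59), miR-23b (-1.71), miR-27b (-2.42), miR-221 (-1.99), miR-130a (-1.79, not above background in spleen DC and at least 2.66-fold lower), miR-181d (-2.62) and miR-181a (-0.44), the last not called without CDP replicate 1 (-0.25). miR-223 was not called (-0.01 ± 0.16, adjusted p = 1) but was lower when scaled over all miRNAs (-0.72).

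The miR-17 family clusters had 10 tested, 0 higher, 10 lower and 0 not called, with 10 called adjusted over the list alone (median log2 difference -1.34, and -1.34 and -1.35 within array designs 1 and 2; camera adjusted p = 1.78e-06, and adjusted p = 0.534 with an estimated correlation), with miR-20b and miR-92a among them and a median of -2.05 when scaled over all miRNAs. The miR-29 family had 3 tested, 3 higher, 0 lower and 0 not called, with 3 called adjusted over the list alone (median log2 difference 2.14, and 2.12 and 2.17 within array designs 1 and 2; camera adjusted p = 0.048, and adjusted p = 0.534 with an estimated correlation), with miR-29b at 1.91 and a median of 1.43 in that scaling. The stem and early progenitor list had 7 tested, 0 higher, 3 lower and 4 not called, with 3 called adjusted over the list alone (median log2 difference -0.54, and -0.52 and -0.57 within array designs 1 and 2; camera adjusted p = 0.0328, and adjusted p = 0.534 with an estimated correlation), with medians of -1.26 when scaled over all miRNAs and -0.99 under quantile normalization. The miR-30 family had 5 tested, 5 higher, 0 lower and 0 not called, with 5 called adjusted over the list alone, camera adjusted p = 0.0808, and a median of 0.70 that turned to -0.01 when scaled over all miRNAs, as did miR-30e (0.70 to -0.01), whose call also ended under quantile normalization (0.08). The let-7 family had 9 tested, 6 higher, 1 lower and 2 not called, with 8 called adjusted over the list alone, camera adjusted p = 0.372, and a median of 0.50 that turned to -0.21 and -0.07 under the other scalings. Of the other lists with fewer than 3 tested members, miR-200b was called higher (0.47 ± 0.15, adjusted p = 0.0218) in the stromal, muscle and epithelial list and miR-200c was not (0.23 ± 0.17, adjusted p = 0.283). miR-370 of the Dlk1-Dio3 locus was called (0.77 ± 0.18, adjusted p = 0.00549) and miR-494 was not (0.26 ± 0.76, adjusted p = 0.819), and miR-486 of the erythroid list was not (0.23 ± 0.12, adjusted p = 0.128). The spleen mean of miR-370 rests largely on CD8+ DC, where it was 1.52 above the mean of the other spleen DC. miR-200b and miR-370 were not above background in CDP and at least 1.07-fold and 1.27-fold higher in spleen DC. Their calls ended without CDP replicate 2 (0.42 and 0.63), that of miR-200b also without CDP replicate 1 (0.51), and that of miR-370 when scaled over all miRNAs (0.58). With normexp 42 miRNAs were called.

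CD8+ DC were compared with the mean of CD4+ and CD4-CD8- DC to find differences between spleen subsets. miR-138 (2.84 ± 0.13, adjusted p = 1.24e-06) and miR-714 (2.47 ± 0.36, adjusted p = 0.00135) rose. miR-138 was not above background in CD4-CD8- DC, so the size of its difference is limited by the floor. miR-365 (1.83 ± 0.16, adjusted p = 8.62e-05) and miR-1224 (1.58 ± 0.12, adjusted p = 4.41e-05) were higher too. miR-34a (-1.39 ± 0.24, adjusted p = 0.00273), miR-125b-5p (-1.36 ± 0.24, adjusted p = 0.00288) and miR-99a (-1.25 ± 0.18, adjusted p = 0.00131) were lower.

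Of 175 miRNAs, 59 were called, 45 higher and 14 lower, with a median log2 difference of 0.19 over all of them. This split depended on the scaling. It was 9 higher and 55 lower when arrays were scaled over all miRNAs (median -0.23), and 22 and 28 under quantile normalization. The percentile over all miRNAs fell near the limit of detection, as 116 to 174 of 604 were detected per array. In each design the count was highest in CD8+ DC (150 and 174). Of the 59 calls, 22 kept direction and threshold under both (9 higher and 13 lower), and 10 turned. The calls numbered 37 without CD8+ DC replicate 1 and 37 without CD8+ DC replicate 2, 32 when only miRNAs detected on all arrays were tested, and 1 with normexp. Others higher were miR-721 (2.01), miR-139-3p (1.96), miR-697 (1.95), miR-188-5p (1.66), miR-1897-5p (1.59) and miR-212 (1.59). The calls of miR-721, miR-1897-5p and miR-212 ended when arrays were scaled over all miRNAs (1.28, 0.84 and 0.87). Without CD8+ DC replicate 1 or 2 the calls of miR-721 (2.22 and 1.81) and miR-1897-5p (1.60 and 1.57) also ended, and the latter ended without CD4+ DC replicate 1 (1.35) or CD4-CD8- DC replicate 1 (1.32). miR-223 was called higher (0.88 ± 0.17, adjusted p = 0.00414) but not when scaled over all miRNAs (0.13). Others lower were miR-28 (-0.94), let-7e (-0.87), miR-322 (-0.85), miR-181a (-0.68), miR-181b (-0.78), miR-340-5p (-0.66) and miR-24 (-0.57). With normexp, miR-28 (0.0293), let-7e (0.00660), miR-181b (0.00155) and miR-340-5p (0.00415) turned to differences near 0 that were not called. Without CD8+ DC replicate 1 or 2 the calls of miR-340-5p (-0.64 and -0.69) and miR-24 (-0.59 and -0.55) ended, and that of miR-188-5p ended without CD8+ DC replicate 1 (1.55). let-7e was not above background in CD8+ DC and at least 1.29-fold lower there, and its call ended when any one of the 6 spleen DC arrays was left out (-0.67 to -1.07) and when arrays were scaled over all miRNAs (-0.93). miR-142-3p, miR-142-5p, miR-146a, miR-21, miR-150, miR-155 and miR-126-3p were not called, and the first 4 of these were called lower when scaled over all miRNAs (-0.90, -0.75, -1.28 and -1.12).

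The probes of the miRNAs called higher in CD8+ DC were rich in G and C, with a median GC content of 59.3 percent against 50 percent for those called lower and 48.5 percent for those not called. Among the 76 miRNAs with a probe GC content above the median of 51.5 percent, 32 were higher and 4 lower. Among the other 99, 13 were higher and 10 lower.

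**Figure D3:**
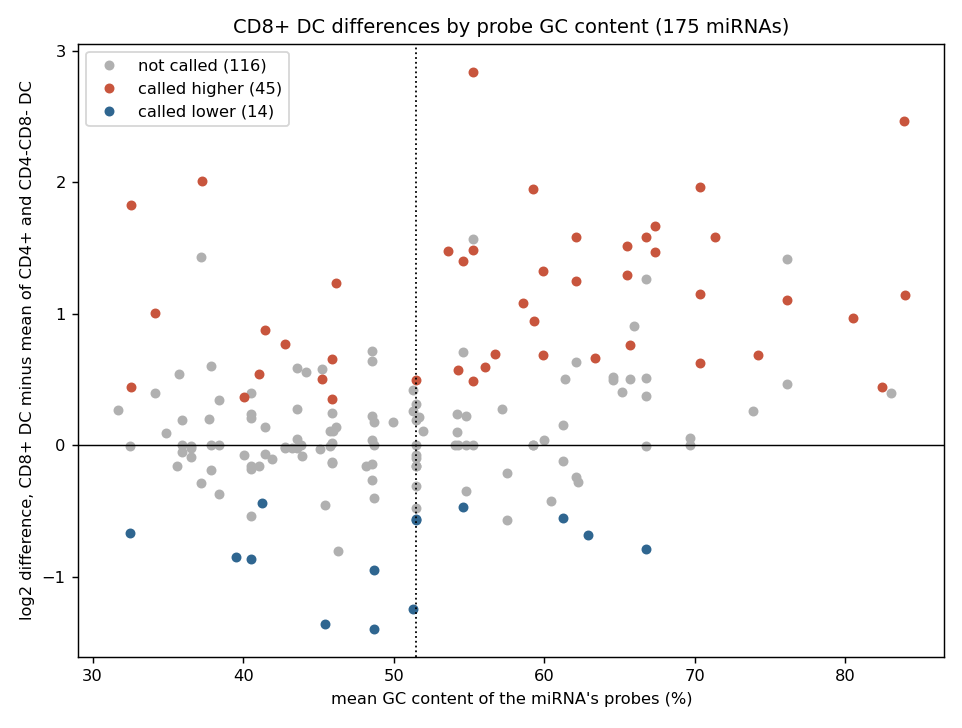
Log2 difference of each of 175 miRNAs (vertical axis, CD8+ DC minus the mean of CD4+ and CD4-CD8- DC) against the mean GC content of its probes in percent. Red points were called higher (45), blue lower (14) and grey not called; the dotted line is the median GC content, 51.5 percent. To its right 32 miRNAs were called higher and 4 lower; the split of all calls turned to 9 higher and 55 lower when arrays were scaled over all miRNAs.

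The stem and early progenitor list had 7 tested, 0 higher, 3 lower and 4 not called, with 3 called adjusted over the list alone in CD8+ DC (median log2 difference -0.80, and -0.37 and -0.76 within array designs 1 and 2; camera adjusted p = 0.00977, and adjusted p = 0.534 with an estimated correlation). The myeloid list had 11 tested, 2 higher, 4 lower and 5 not called, with 7 called adjusted over the list alone (median log2 difference -0.53, and -0.21 and -0.55 within array designs 1 and 2; camera adjusted p = 0.0308, and adjusted p = 0.534 with an estimated correlation), with miR-322 and miR-34a lower and miR-212 and miR-223 higher, and its median was -1.28 when scaled over all miRNAs. The lymphocyte list had 7 tested, 0 higher, 2 lower and 5 not called, with 3 called adjusted over the list alone (median log2 difference -0.40, and 0.00 and -0.72 within array designs 1 and 2; camera adjusted p = 0.0326, and adjusted p = 0.534 with an estimated correlation), with miR-181b and miR-181a as examples. For the activation list, 6 tested, 2 higher, 0 lower and 4 not called, with 2 called adjusted over the list alone, the median was -0.09 and the mean 0.18, and camera gave adjusted p = 0.946. miR-486 (0.69 ± 0.12, adjusted p = 0.00288) and miR-370 (1.52 ± 0.19, adjusted p = 0.00077) were called higher, and miR-451 (1.43 ± 0.94, adjusted p = 0.261) and miR-494 (1.57 ± 0.81, adjusted p = 0.156) were not. The difference of miR-486 equalled its range over all populations, 0.69, so the other spleen DC lay at its lowest value. The floor leaves little spread there, and the SE of miR-486 can be too small. miR-486 was not above background in CD4+ and CD4-CD8- DC and at least 1.3-fold higher in CD8+ DC, and its call ended under both other scalings (0.23 over all miRNAs and 0.22 with quantile normalization).

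CD4+ and CD4-CD8- DC differed little. miR-138 was higher in CD4+ DC (1.00 ± 0.15, adjusted p = 0.0167) and, not above background in CD4-CD8- DC, at least 1.48-fold so. Lower in CD4+ DC were miR-221 (-0.88 ± 0.16, adjusted p = 0.0313), miR-23a (-0.80 ± 0.17, adjusted p = 0.0313) with miR-23b (-0.74 ± 0.15, adjusted p = 0.0313), and miR-181c (-0.89 ± 0.19, adjusted p = 0.0313). Of 175 miRNAs, 8 were called, 1 higher and 7 lower, the others being miR-92a (-0.55), miR-181a (-0.60) and miR-181b (-0.64). miR-155 (-1.36 ± 0.36, adjusted p = 0.065) was not called, nor were the other miRNAs named in every comparison apart from miR-181a. The miR-17 family clusters had 10 tested, 0 higher, 1 lower and 9 not called, with 3 called adjusted over the list alone (median log2 difference -0.38, and -0.49 and -0.27 within array designs 1 and 2; camera adjusted p = 0.000999, and adjusted p = 0.534 with an estimated correlation), with miR-92a and miR-18a as examples. The lymphocyte list had 7 tested, 0 higher, 3 lower and 4 not called, with 4 called adjusted over the list alone (median log2 difference -0.85, and -0.68 and -0.94 within array designs 1 and 2; camera adjusted p = 0.00321, and adjusted p = 0.534 with an estimated correlation), and the miR-29 family 3 tested, 0 higher, 0 lower and 3 not called, with 2 called adjusted over the list alone (median log2 difference 0.37, and 0.52 and 0.28 within array designs 1 and 2; camera adjusted p = 0.0308, and adjusted p = 0.534 with an estimated correlation), with miR-29a (0.37) and miR-29b (0.59) as examples. Of the 8 calls, 0 were made under both other scalings: 0 miRNAs were called when arrays were scaled over all miRNAs and 8 under quantile normalization. Scaled over all miRNAs, the differences themselves changed little, with 1.09 for miR-138 (adjusted p = 0.0546), -0.83 for miR-221 (adjusted p = 0.105) and -0.76 for miR-23a (adjusted p = 0.111). With normexp the difference of miR-138 shrank to 0.02 and that of miR-181c to -0.34. Those of miR-221 (-0.58) and miR-23a (-0.74) changed less. Leaving out CD4-CD8- DC replicate 2 left 0 calls, CD4+ DC replicate 1 left 2 and CD4+ DC replicate 2 left 1, 0 were called with normexp or without the block on the array design, and 5 after a line of signal against probe GC content was removed from each array, a step chosen after seeing the data.

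PDC were compared with the mean of the spleen DC to contrast plasmacytoid with conventional cells, with marrow against spleen as an added difference. The miR-181 family was higher in PDC, led by miR-181b (2.68 ± 0.12, adjusted p = 6.53e-07) and miR-181a (2.35 ± 0.10, adjusted p = 6.53e-07). miR-128 (3.40 ± 0.22, adjusted p = 3.52e-06), miR-362-3p (3.33 ± 0.23, adjusted p = 4.25e-06) and miR-148a (2.41 ± 0.11, adjusted p = 6.53e-07) were higher too. miR-34a (-4.27 ± 0.23, adjusted p = 1.22e-06), miR-223 (-2.40 ± 0.16, adjusted p = 4.25e-06), miR-155 (-1.94 ± 0.29, adjusted p = 0.000709) and miR-146a (-1.78 ± 0.25, adjusted p = 0.000466) were lower.

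Of 175 miRNAs, 75 were called, 32 higher and 43 lower (median log2 difference -0.13 over all). The split was 32 higher and 22 lower when scaled over all miRNAs, and 42 and 36 under quantile normalization, and 53 calls kept direction and threshold under both (31 higher and 22 lower). Others higher were miR-532-5p (2.83), miR-532-3p (2.10), miR-592 (2.61), miR-181c (2.24), miR-181d (2.53) and miR-126-3p (1.90). miR-592 and miR-126-3p were not above background in spleen DC and at least 4.71-fold and 2.89-fold higher in PDC. Others lower were miR-21 (-1.74), miR-342-3p (-1.71), miR-22 (-1.62), miR-1224 (-1.47), miR-151-5p (-1.38), miR-142-3p (-0.77) and miR-142-5p (-0.73), and miR-138, not above background in PDC, was at least 1.67-fold lower. Among spleen DC, miR-1224 and miR-138 were higher in CD8+ DC than in the others (1.58 and 2.84). In CD4-CD8- DC miR-138 was not above background either, so its pooled difference does not hold for each spleen population. The calls of miR-142-3p and miR-142-5p ended when scaled over all miRNAs (-0.57 and -0.54), that of miR-142-3p also under quantile normalization (-0.27) and that of miR-142-5p without PDC replicate 1 (-0.51). miR-150 was not called. The lymphocyte list had 7 tested, 4 higher, 1 lower and 2 not called, with 5 called adjusted over the list alone (median log2 difference 2.24, and 2.11 and 2.37 within array designs 1 and 2; camera adjusted p = 0.0211, and adjusted p = 0.534 with an estimated correlation), the 4 higher members being the miR-181 family. The myeloid list had 11 tested, 0 higher, 7 lower and 4 not called, with 7 called adjusted over the list alone (median log2 difference -0.84, and -0.54 and -1.14 within array designs 1 and 2; camera adjusted p = 0.0328, and adjusted p = 0.534 with an estimated correlation), with miR-34a, miR-223 and miR-22 as examples. With normexp 16 miRNAs were called.

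Gr1+ monocytes were compared with the mean of the spleen DC, again marrow against spleen. miR-223 was higher in monocytes (1.72 ± 0.16, adjusted p = 4.29e-05), though not past the threshold under quantile normalization (0.45). miR-27a (1.92 ± 0.21, adjusted p = 0.000117) and miR-148a (1.79 ± 0.11, adjusted p = 3.9e-06) were higher as well. Lower in monocytes were miR-146a (-5.25 ± 0.25, adjusted p = 9.88e-07), miR-34a (-4.66 ± 0.23, adjusted p = 9.88e-07) and miR-155 (-4.06 ± 0.29, adjusted p = 8.81e-06), the last not above background in monocytes and at least 12-fold lower there.

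Of 175 miRNAs, 72 were called, 30 higher and 42 lower (median log2 difference -0.10 over all). The split was 31 higher and 19 lower when scaled over all miRNAs, and 40 and 26 under quantile normalization, and 45 calls kept direction and threshold under both (28 higher and 17 lower). Others higher were miR-27b (1.78), miR-378 (1.61), miR-322 (1.24), miR-18a (1.23), miR-10a (1.20), miR-139-5p (1.13) and miR-17 (1.05). Without monocyte replicate 1 the calls of miR-10a (0.84) and miR-139-5p (1.31) ended, and that of miR-139-5p also ended without monocyte replicate 2 (0.94). Others lower were miR-151-5p (-3.83, not above background in monocytes and at least 10.3-fold lower), miR-150 (-3.53), miR-342-3p (-2.14), miR-142-5p (-1.03), miR-142-3p (-0.94), miR-181a (-0.63) and the erythroid miR-451 (-3.58). The call of miR-451 ended without monocyte replicate 1 (-2.84) and that of miR-181a under quantile normalization (-0.08) and with normexp, where it turned (0.08). miR-21 and miR-126-3p were not called. With normexp, miR-126-3p, not above background on either side, was called higher in monocytes (0.98, adjusted p = 0.0275). The miR-29 family had 3 tested, 0 higher, 3 lower and 0 not called, with 3 called adjusted over the list alone (median log2 difference -1.62, and -1.79 and -1.54 within array designs 1 and 2; camera adjusted p = 0.015, and adjusted p = 0.534 with an estimated correlation), with miR-29a (-1.62), miR-29b (-1.49) and miR-29c (-2.06). For the miR-17 family clusters there were 10 tested, 6 higher, 0 lower and 4 not called, with 6 called adjusted over the list alone (median log2 difference 0.44, and 0.54 and 0.39 within array designs 1 and 2; camera adjusted p = 0.000381, and adjusted p = 0.534 with an estimated correlation), with miR-93 (0.92) and miR-20a (0.66) beside miR-18a and miR-17. With normexp 125 miRNAs were called, 113 higher and 12 lower.

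The mean of the 5 differentiated populations was compared with the mean of the 3 progenitor populations. All 3 progenitors came from marrow and 3 of the 5 differentiated populations from spleen, so tissue changes in part with stage. Pool size went with the division as well. So did the column of the slide, apart from CD8+ DC, which lay in the column of the progenitors. miR-146a (3.81 ± 0.16, adjusted p = 7.42e-08), miR-342-3p (3.32 ± 0.15, adjusted p = 1.01e-07), miR-150 (2.94 ± 0.29, adjusted p = 1.59e-05) and miR-22 (4.49 ± 0.11, adjusted p = 7.58e-09) rose. miR-22 was detected on 2 and miR-150 on 4 of the 6 progenitor arrays, so the size of their differences is limited by the floor. Both arms of miR-142 rose (miR-142-5p 1.70 ± 0.09, adjusted p = 2.86e-07; miR-142-3p 1.26 ± 0.10, adjusted p = 3.47e-06). The progenitor miRNAs miR-126-3p (-2.81 ± 0.11, adjusted p = 7.42e-08), miR-130a (-2.74 ± 0.17, adjusted p = 8.12e-07) and miR-196b (-2.41 ± 0.11, adjusted p = 1.08e-07) fell, and so did miR-17 (-1.92 ± 0.09, adjusted p = 1.08e-07) and miR-20a (-1.71 ± 0.06, adjusted p = 6.06e-08), members of clusters known from dividing cells.

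Of 175 miRNAs, 110 were called, 67 higher and 43 lower, with a median log2 difference of 0.14 over all. The split was 46 higher and 49 lower when scaled over all miRNAs, and 56 and 47 under quantile normalization, and 87 calls kept direction and threshold under both (45 higher and 42 lower). Others higher were miR-151-5p (not above background in any progenitor), miR-451 (2.23), miR-34a (1.93), miR-532-5p (1.79), miR-29c (1.65) and miR-21 (1.03). Not every miRNA higher in the mean rose in each differentiated population. miR-34a had its lowest mean in Gr1+ monocytes, where miR-151-5p was not above background. In monocytes against MDP, miR-146a and miR-150 were not called. Others lower were miR-181d (-2.19), miR-181b (-1.86), miR-18a (-1.83), miR-27b (-1.73) and miR-221 (-1.70). In PDC against CDP, miR-181d and miR-181b were not called. miR-155 was not called, nor were miR-181a (-0.06) and miR-223 (-0.21), both of which were called lower under both other scalings (-0.28 and -0.17; -0.44 and -0.63). The miR-17 family clusters had 10 tested, 0 higher, 10 lower and 0 not called, with 10 called adjusted over the list alone (median log2 difference -1.53, and -1.42 and -1.64 within array designs 1 and 2; camera adjusted p = 6.25e-06, and adjusted p = 0.534 with an estimated correlation), with miR-92a (-1.45) and miR-20b (-1.66) as further examples. The stem and early progenitor list had 7 tested, 0 higher, 6 lower and 1 not called, with 6 called adjusted over the list alone (median log2 difference -1.40, and -1.32 and -1.52 within array designs 1 and 2; camera adjusted p = 0.00137, and adjusted p = 0.534 with an estimated correlation). Camera passed no other list here. The miR-29 family had 3 tested, 3 higher, 0 lower and 0 not called, with 3 called adjusted over the list alone (adjusted p = 0.0625), the miR-15 and miR-16 family 5 tested, 4 higher, 1 lower and 0 not called, with 5 called adjusted over the list alone (adjusted p = 0.217), the miR-30 family 5 tested, 5 higher, 0 lower and 0 not called, with 5 called adjusted over the list alone (adjusted p = 0.116), the activation list 6 tested, 3 higher, 2 lower and 1 not called, with 5 called adjusted over the list alone (adjusted p = 0.946) and the lymphocyte list 7 tested, 2 higher, 3 lower and 2 not called, with 5 called adjusted over the list alone (adjusted p = 0.488). In the lymphocyte list the median (-0.06) and the mean (0.24) differed in sign, and camera set the activation list lower although its median (0.34) and mean (0.42) were above 0. The myeloid list had 11 tested, 4 higher, 3 lower and 4 not called, with 7 called adjusted over the list alone (adjusted p = 0.946), with a median of 0.10 that turned to -0.12 when scaled over all miRNAs. With normexp 56 miRNAs were called.

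**Figure D4:**
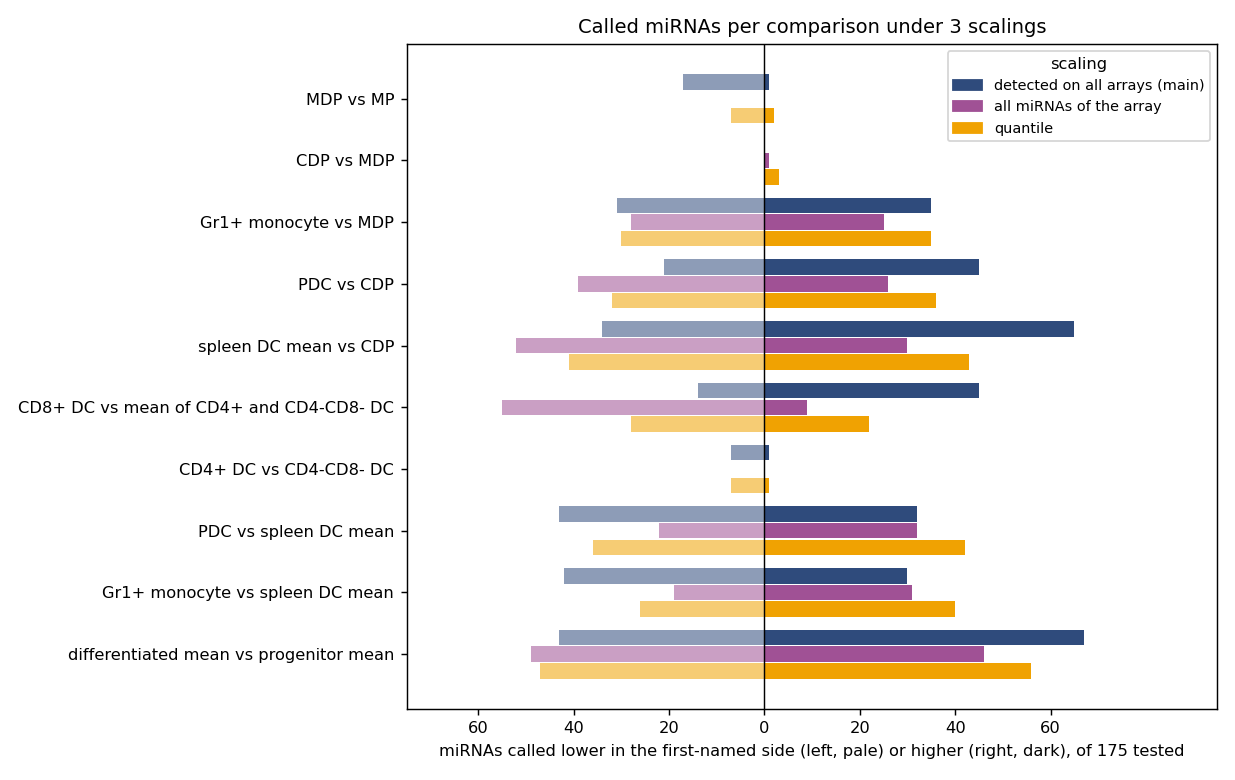
Number of miRNAs called per comparison, of 175 tested, under 3 scalings of the arrays: the 75th percentile over the miRNAs detected on all arrays, that over all miRNAs of the array, and quantile normalization within each design. Dark bars to the right count miRNAs higher in the side named first, pale bars to the left those lower. For CD8+ DC the split turns from 45 higher and 14 lower to 9 and 55 when arrays are scaled over all miRNAs.

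Over all comparisons, 9 fixed lists with at least 3 tested members gave 90 list tests. Camera with its preset correlation passed 26 of them, fry passed 23 of these 26, and 0 passed with a correlation estimated from the data. The median, the mean and the direction of the camera test did not all share a sign for the myeloid list in PDC against CDP (median -0.21, mean 0.14, adjusted p = 0.287) and in monocytes against spleen DC (median 0.27, mean -0.31, adjusted p = 0.193), for the lymphocyte list in spleen DC against CDP (median -0.44, mean 0.07, adjusted p = 0.217) and for the activation list in PDC against CDP, tested as lower (median 0.11, mean 0.48, adjusted p = 0.782). None of these passed. Among the values given for named miRNAs, 233 were calls. Normexp background correction ended 102 of them, and in 12 of these 102 the direction turned as well. Leaving the array design out of the model ended 28 calls, among them calls of miR-142-3p in monocytes against MDP (adjusted p = 0.447), in PDC against CDP (adjusted p = 0.559) and in PDC against spleen DC (adjusted p = 0.277).

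**Figure D5:**
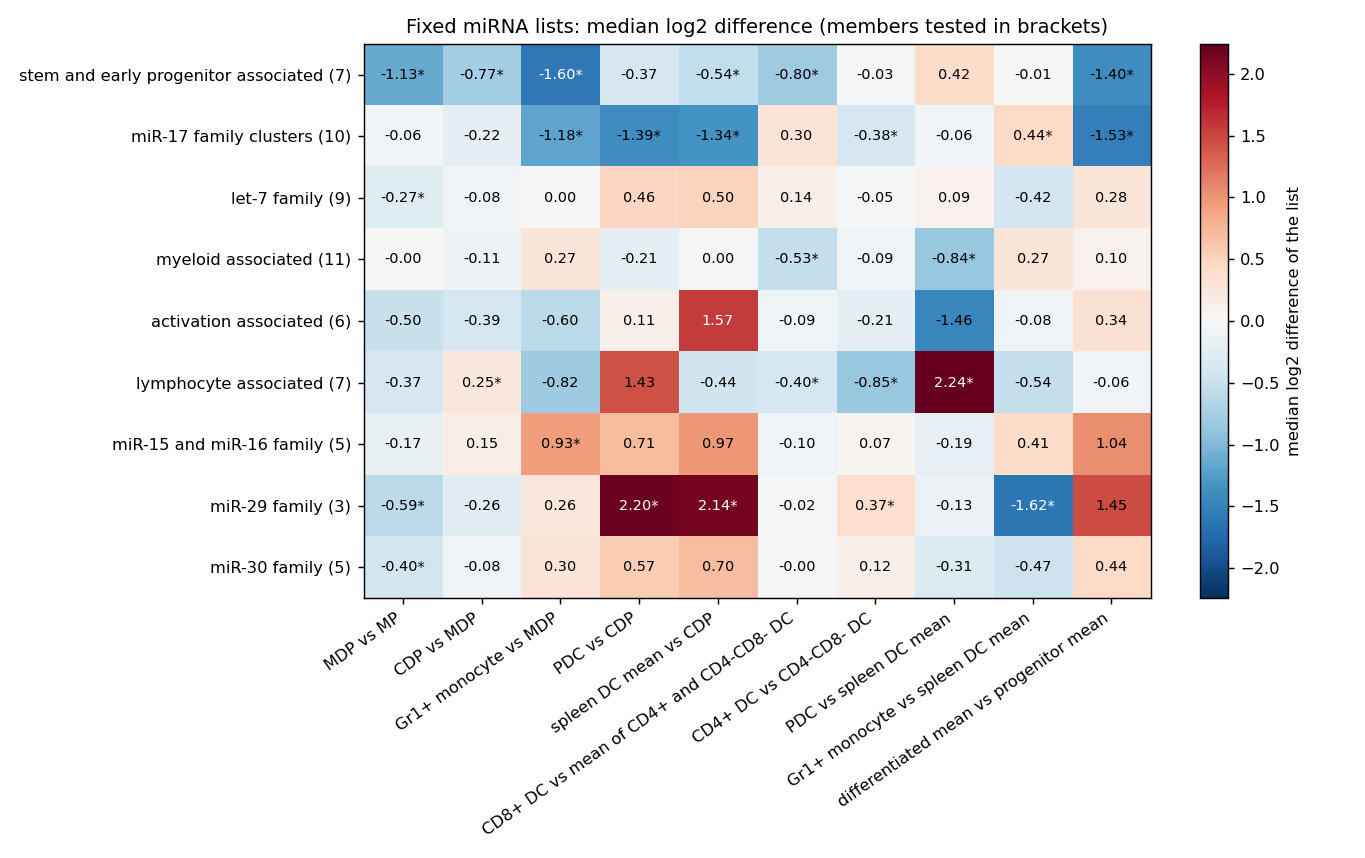
Median log2 difference of 9 fixed miRNA lists (vertical axis, number of tested members in brackets) in the 10 comparisons (horizontal axis, first side minus second). A star marks a camera adjusted p under 0.05 with the preset correlation. The miR-17 family clusters have medians of -1.18, -1.39 and -1.34 in Gr1+ monocytes, PDC and spleen DC against their progenitors; among the starred lists the let-7 and miR-30 medians of MDP against MP turn under another scaling.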

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

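The tests of the GC content of the probes and of erythroid RNA were chosen only after the results they examine had been seen. The splits of the samples and the tests of scaling and of slide position were set out before.

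Signal appeared in data outside the comparisons. Of 39 viral miRNAs on design 1, 3 were detected on all 8 of its arrays: mcmv-miR-M23-1-5p (signals 13.4 to 30.7), mcmv-miR-m01-2 (28.7 to 130) and mghv-miR-M1-2 (34.0 to 46.1). After scaling, the first and last were highest in CD8+ DC replicate 1 and mcmv-miR-m01-2 in CD4+ DC replicate 1. CD8+ DC replicate 1 had 5 viral miRNAs detected, the other arrays 3 or 4. It also had the lowest scaling factor of design 1 (392). Whether such signal is specific to the named miRNA was not tested. Of 92 miRNAs carried by design 2 alone, 23 were detected on all 8 of its arrays. After scaling, 20 of these were highest in CD8+ DC, and 22 lay above the mean of CD4+ and CD4-CD8- DC there, with a median log2 difference of 1.16. These have 1 array per population and were not tested.

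The calls of CD8+ DC against the other spleen DC were mostly higher, 45 of 59. The filter adds to this, since a miRNA detected in CD8+ DC alone was tested and could only come out higher. CD8+ DC had the most miRNAs detected in each design (150 and 174) and the fewest tested ones at the floor (26 and 21). For miR-138*, called higher, the difference in CD8+ DC equalled its range over all populations, 0.68. When a straight line of signal against the GC content of the probes was removed from each array, 79.1 percent of the calls were higher, 53 of 67. The line turned about the mean GC content, so the mean difference over all tested miRNAs stayed at 0.31, and the share decides nothing. With the mean of each array removed as well the share was 44.8 percent, a step that takes out the shift itself. A signal that rises in a straight line with GC content and a broad rise in the cells cannot be told apart by these steps. A signal raised in GC-rich probes may account for the excess, since among miRNAs with GC content at or below the median 56.5 percent of the calls were higher and above it 88.9 percent. The bound for this split was set after calls by GC content had been looked at, which makes it a description more than a test.

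Scaling may also account for the excess in CD8+ DC, as 44.0 percent of the calls were higher under quantile normalization, and 9 were higher and 55 lower when arrays were scaled over all miRNAs. Quantile normalization would also remove a real broad rise. The percentile over all miRNAs fell near the limit of detection, since most miRNAs were not detected on an array. Both CD8+ DC arrays lay at the same slide position, where 0 arrays of other populations lay, so position and population cannot be told apart. The same holds for MP, MDP, CDP and Gr1+ monocytes, each at its own position on both slides. The gate on CD86, which the labels give for CD8+ DC and for no other DC, stays open as an untested biological difference.

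Splits of the samples asked whether chance can give as many calls for differentiated against progenitor cells. Of 100 splits of the 16 samples in a 2-group model, 1 gave as many calls as the real one, the real one itself, with 75 against at most 7 in the others. Those splits part the replicates of a population. With populations kept whole, the same model gave 70 calls for the 3 spleen DC populations against the rest. Of the 56 splits of the 8 populations, 1 gave as many, again the real one, with 110 calls. The highest other split gave 108, so the populations differ in many ways and the count says little about this division in particular.

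miR-451, an erythroid miRNA, was higher in spleen DC than in CDP (3.67 ± 0.88, adjusted p = 0.00598). Carry-over of erythroid RNA may be a source but cannot be told apart from a change in the cells, since the other erythroid list member tested, miR-486, differed by 0.23 and was detected on few arrays. The lineage gate with Ter-119 was applied to the progenitors, which leaves the sorting as a difference between the sides.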

How the results depend on the processing

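The removal of the GC trend and the omission of both CD8+ DC arrays were chosen after seeing the data; the other alternatives were set before. Over the alternatives set before, values of named miRNAs stayed on their side of the threshold in 4663 cases. The call was lost without a turn of direction in 302 and gained in 23, and the direction turned in 16. A turn was counted only for values called in the main setting or in the alternative. Uncalled values that changed sign are therefore among the 4663, and values of the F test have no direction. For lists, under the same rule, the numbers were 452, 51, 35 and 2. The series tables changed no count. Where results changed below, the cause was not tested. Dim miRNAs limit the comparisons, with 21 to 56 of 175 at the floor per array.

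Scaled over all miRNAs, MDP vs MP had 0 calls, CDP vs MDP 1 and CD4+ vs CD4-CD8- DC 0, and in spleen DC vs CDP miR-30e (-0.0144) and let-7a (-0.142) turned. With quantile normalization MDP vs MP had 9 and CDP vs MDP 3, let-7a turned in spleen DC vs CDP (-0.0653), and the miR-30 family in MDP vs MP (camera adjusted p = 0.801). With fry, the activation list in CD8+ DC passed (adjusted p = 0.0376) in a direction other than that of camera. This was counted as a turn, though the tests ask different questions, fry against no change and camera against the other miRNAs. The brightest probe gave 9 for MDP vs MP.

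With normexp the counts were 0 for MDP vs MP, 11 for Gr1+ monocyte vs MDP, 31 for PDC vs CDP, 42 for spleen DC vs CDP, 1 for CD8+ DC, 0 for CD4+ vs CD4-CD8- DC, 16 for PDC vs spleen DC, 125 for Gr1+ monocyte vs spleen DC, 56 for differentiated vs progenitor and 53 among the 8 populations. Turned under it were miR-450a-5p in MDP vs MP (0.0194); miR-196b (0.0825), miR-155 (0.191), miR-181d (0.00523), miR-181c (0.277), miR-99a (0.332) and miR-125b-5p (0.0519) in Gr1+ monocyte vs MDP; miR-28 (0.0293), let-7e (0.00660), miR-181b (0.00155) and miR-340-5p (0.00415) in CD8+ DC; and miR-181a (0.0849) and miR-126-3p (0.978) in Gr1+ monocyte vs spleen DC. Of these, miR-126-3p alone was called (adjusted p = 0.0275). The offset of normexp limits what these counts and turns say about dim miRNAs, as given above. Testing only the 88 miRNAs detected on all arrays gave 32 for CD8+ DC and 81 among the 8 populations, with fewer miRNAs tested.

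Without the replicate block the counts were 9 for MDP vs MP, 0 for CDP vs MDP, 50 for Gr1+ monocyte vs MDP, 57 for PDC vs CDP, 86 for spleen DC vs CDP, 41 for CD8+ DC, 0 for CD4+ vs CD4-CD8- DC, 54 for PDC vs spleen DC, 56 for Gr1+ monocyte vs spleen DC, 99 for differentiated vs progenitor and 101 among the 8 populations.

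Leaving out 1 array at a time, with the lone array of a population assumed to vary like the others, gave 0 to 15 calls for MDP vs MP, 0 to 0 for CDP vs MDP, 50 to 63 for Gr1+ monocyte vs MDP, 58 to 68 for PDC vs CDP, 81 to 104 for spleen DC vs CDP, 37 to 60 for CD8+ DC, 0 to 11 for CD4+ vs CD4-CD8- DC, 63 to 76 for PDC vs spleen DC, 51 to 78 for Gr1+ monocyte vs spleen DC, 104 to 115 for differentiated vs progenitor and 118 to 130 among the 8 populations. With both CD8+ DC arrays left out the counts were 88 for spleen DC vs CDP, 62 for PDC vs spleen DC, 60 for Gr1+ monocyte vs spleen DC, 105 for differentiated vs progenitor and 104 among the populations. The GC trend removed, CD8+ DC had 67, CD4+ vs CD4-CD8- DC 5 and MDP vs MP 14, and the 2-group model gave 75 for differentiated vs progenitor.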

Other observations

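Neighbouring miRNAs on chromosome X, within 50 kb of miR-532-5p, were chosen after their values were seen. Of 9 miRNAs named in this window, 7 were tested, with probes from 6814874 to 6825606 (build mm9). Of the 7 tested, 5 were called higher in PDC than in CDP and 5 higher than in the spleen DC. miR-362-3p, miR-532-3p and miR-362-5p were not above background in CDP and at least 13.7-fold, 3.33-fold and 2.17-fold higher in PDC. miR-500, detected on both CDP arrays, differed by 3.18. miR-532-5p differed by 4.12, a size limited by the floor, as it was detected on 1 of the 2 CDP arrays. miR-501-3p (0.14) and miR-188-5p (-0.34) were not called. In CD8+ DC, miR-188-5p was called higher (1.66 ± 0.32, adjusted p = 0.00414) and the other 6 tested members were not called.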
